A study of Drosophila melanogaster with 42 samples.

How the data were processed

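RNA of whole Drosophila melanogaster animals was measured in 42 libraries, 3 for each of 2 genotypes (control and ERR mutant) at each of 7 stages, which the labels name WPP, P1, P2, P3, P4, A1 and A6. Per the labels' protocols, every animal received a heat treatment, the genotypes differed in whether an hsFLP transgene was present, and staging started from WPP. Poly(A) RNA was made into stranded Illumina TruSeq libraries. The group of each library was taken from its genotype and time point labels. The labels do not state whether the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

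The authors deposited a workbook made with tools that the submitters' processing notes name without roles or order: cutadapt 1.16, STAR 2.7.0f, RSEM 1.3.1 and DESeq2 1.22.2, with genome build dm6. The annotation, the strand setting of the counting and any filter were not given in the sources used here. The deposited estimated counts per gene were already whole numbers, covered 15038 genes and were used as they stand. The deposited normalized signal holds those counts divided by a factor for each gene and library, and these factors entered only as an alternative scaling. The deposited FPKM and log-scale values were not used here.

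Library totals ranged from 4308848 to 7737140 counts. Counting error is therefore small for abundant genes, and a gene at 1 CPM (counts scaled to the library total after TMM scaling) rests on a few counts in each library. Replicates were compared first: over the 42 pairs of replicates, the chi-square statistic per gene lay between 2.86 and 71.8, so no pair agreed within sampling noise and none was counted as 1 sample.

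Counts were tested with edgeR 4.0.16 in R 4.3.3. All 42 libraries entered 1 fit of 14 groups with TMM scaling and the filterByExpr filter, which left 13672 genes and 28 residual degrees of freedom. The quasi-likelihood test with robust dispersion gave log2 fold changes with standard errors (SE), and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene is called when its adjusted p lies under 0.05, with no fold threshold. The comparisons were the ERR mutant against the control at each stage, each control stage against the next, the genotype by stage interaction, and the mean effect at A1 and A6 minus the mean effect at P1 to P4. The last reads A as adult and P as pupal, which the labels do not spell out. Levels are CPM after TMM scaling, as mean ± SD over 3 libraries. A fold against a group with 0 counts is a bound that sets the group at 3 counts in all.

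A total of 36 gene lists were fixed before the data were examined, covering metabolic pathways, organelles, and markers of tissues and sexes that whole animals hold. Each was tested at each stage with limma 3.58.1's camera at a preset correlation between genes of 0.01, adjusted over 252 tests of lists and stages, and over 216 tests for the control steps. Counts of called members are given over all genes tested, and also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. Camera compares a list with all other genes, while fry asks whether the members move, on balance, one way.

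Named genes followed a rule set at the same time: ERR, and at each stage the 5 genes higher and 5 lower with the largest fold among called genes. Those had a mean of at least 5 CPM and no overlap between the 3 mutant and 3 control libraries, a separation that chance gives in 10% of splits of 3 against 3. The rule added up to 4 members of each list by adjusted p, at most 2 of them against the list's median, and up to 10 genes called in 1 direction at all stages. It also took the 5 genes with the smallest interaction p, the 5 largest differences in each direction between A and P stages, and the 3 largest changes in each direction at each control step. Of the genes so selected, the text gives those that describe each group.

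Each library was also placed on the control time course by its log2 CPM profile (prior count 2) over genes that change between control stages, with control libraries left out of their own mean. Positions of 3 mutant and 3 control libraries were compared with a two-sided exact permutation test, whose smallest possible p is 0.1. Gene positions were taken from the Ensembl release 115 annotation BDGP6.54, which uses the dm6 coordinates, and 99.4% of the deposited identifiers were found in it. Genes that overlap or share near-identical sequence can share reads, so their values are uncertain.

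On simulated counts for the A1 comparison over 13586 genes, 70% of 100 genes changed 2-fold and 95% of 100 genes changed 4-fold were called, all in the right direction, with 12 false calls. The 6 stages with no simulated change gave 0 calls. The changed genes were drawn from those with a mean of at least 5 CPM at A1, so recovery at lower levels was not tested. The simulated libraries varied independently within a group, so these false calls do not cover a structure shared by real samples. Alternatives set before the data were examined were DESeq2's size factors in edgeR, DESeq2 1.42.0 itself, no low-count filter, a 2-fold threshold, only the 6 libraries compared, and each library left out in turn. Scaling by the deposited factors, and leaving out 1 library of the mutant P1 group from every comparison, were added after the data were seen.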

Results

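RNA was measured in whole flies along a course from the stage labelled WPP, through P1 to P4, to A1 and A6, in a control genotype and in a mutant of ERR, the single fly member of the estrogen-related receptor family of nuclear receptors. The series title places the work in a developmental switch that supports glycolysis and lipid synthesis in the adult. The comparisons ask which genes differ between the ERR mutant and the control at each stage, and how the same genes move in controls. The genotypes also differed in whether an hsFLP transgene was present, so a difference between them cannot be assigned to ERR alone. Each of the 14 groups held 3 libraries of 4308848 to 7737140 counts. Levels below are CPM (counts scaled to the library total after TMM scaling), mean ± SD, n = 3 unless another n is given.

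ERR itself (FBgn0035849, chromosome 3L, 8183361 to 8186671 on the minus strand, dm6) was called lower in the mutant at the last 3 stages. At A6 its level was 35.6 ± 1.36 CPM in controls and 5.46 ± 0.821 CPM in mutants, a 6.49-fold difference (log2 fold change -2.70, SE 0.189, adjusted p = 2.8e-12). At P4 it was 23.4 ± 4.32 against 8.86 ± 0.993 CPM, and at A1 18.5 ± 0.984 against 7.46 ± 0.958 CPM (adjusted p = 1.7e-05 and 2.7e-05). At WPP, P1, P2 and P3 the log2 differences were -0.59, -0.60, -0.43 and -0.79, and none passed when adjusted over all genes (adjusted p = 0.176, 0.135, 0.137 and 0.101). Adjusted over the 7 stages of this gene alone, these 4 differences passed (adjusted p = 0.00294, 0.00294, 0.0250 and 9.1e-04). At each of the 7 stages the 3 mutant libraries lay below the 3 control libraries. Chance gives a separation in either direction in 10% of splits at 1 stage. Over all genes, the P3 difference passed with DESeq2's size factors in edgeR (adjusted p = 0.0498) and not with DESeq2 itself (adjusted p = 0.0750). The labels do not say which part of the gene the mutation affects, so the remaining reads do not show how much working ERR was left.

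**Figure D1:**
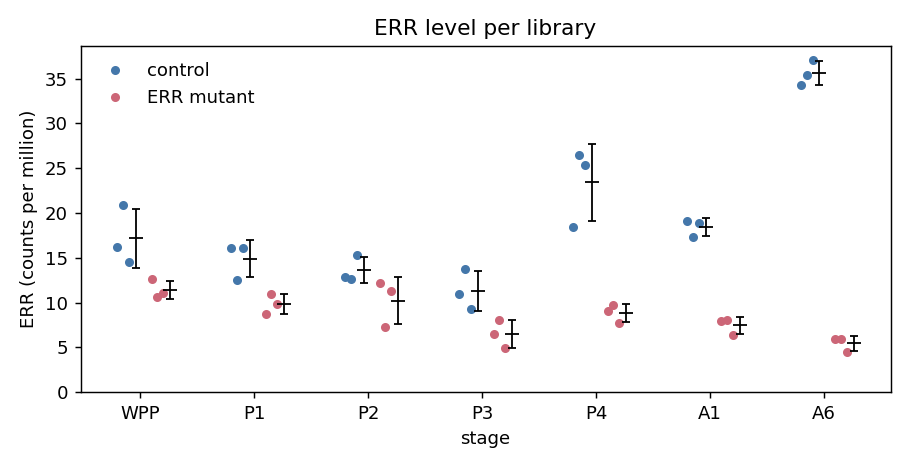
ERR level in CPM in each of the 42 libraries, by stage and genotype, with the mean ± SD of 3 libraries in black. Controls reached 35.6 ± 1.36 CPM at A6, where mutants were at 5.46 ± 0.821 CPM.

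Genes of glycolysis, the pathway that breaks glucose down to pyruvate, were lower in the ERR mutant at every stage tested. Of the 13 members of the list, 13, 11, 11, 11, 10, 10 and 10 fell from WPP to A6, and 13, 12, 11, 11, 11, 12 and 11 when adjusted over the list alone. The median log2 fold changes were -1.11, -0.98, -1.50, -1.55, -1.22, -1.42 and -1.40, and no member was called higher. Mutant P1 replicate 1 enlarged the P1 value. Relative to control WPP the P1 mutant libraries had medians of -1.642, -0.992 and -0.935 in order of replicate, against a mean of -0.333 in P1 controls. At P2, Gapdh1, a glyceraldehyde-3-phosphate dehydrogenase, was at 860.6 ± 66.3 CPM in controls and 218.1 ± 35.7 CPM in mutants (3.95-fold lower, adjusted p = 3.0e-13). At A1, Pgm, which interconverts glucose phosphates at the entry to glycogen, was at 369.1 ± 2.18 against 67.4 ± 8.43 CPM, and Pgk, phosphoglycerate kinase, at 581.6 ± 37.5 against 136.8 ± 8.54 CPM. In controls the median member was 1.91 log2 units above its WPP level at P3 and 2.69 above at A1, and in mutants 0.43 and 1.30 above the control WPP level. The list test (camera) gave adjusted p between 5.7e-185 and 6.2e-51 at the 6 stages other than P1 and 2.0e-39 at P1. All 7 calls held with an estimated correlation (adjusted p from 6.1e-11 at P3 to 5.1e-05 at P1).

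A total of 13 genes were called in 1 direction at all 7 stages, and 9 of them encode glycolysis enzymes: Gapdh2, Pgm, Pgk, Pglym78, Gapdh1, Tpi, Pgi, Eno and Ald. Their mean log2 fold changes over stages ranged from -1.95 for Gapdh2 to -0.97 for Ald. The others were mthl7, a predicted receptor of the methuselah family, and Kmn1, a kinetochore protein, both higher, and eIF4E7, a cap-binding translation factor, and CG14024, both lower. Kmn1 overlaps CG11699, so its values are uncertain. There were exceptions when libraries were left out. Pgi at P1 was no longer called without control P1 replicate 2 (adjusted p = 0.228) or mutant P1 replicate 1 (0.155). Gapdh1 at WPP was lost without control WPP replicate 1 or 2 or mutant WPP replicate 1 or 3 (adjusted p from 0.0661 to 0.195), and Kmn1 at P4 without control P4 replicate 1 or 2 or mutant P4 replicate 1 or 2 (from 0.0776 to 0.188). With only the 6 libraries of a stage fitted, Pgm at WPP and P1, Tpi, Pgi and eIF4E7 at P1, Gapdh1 at WPP, and Kmn1 at P3 and P4 were not called (adjusted p from 0.0927 to 0.732).

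**Figure D2:**
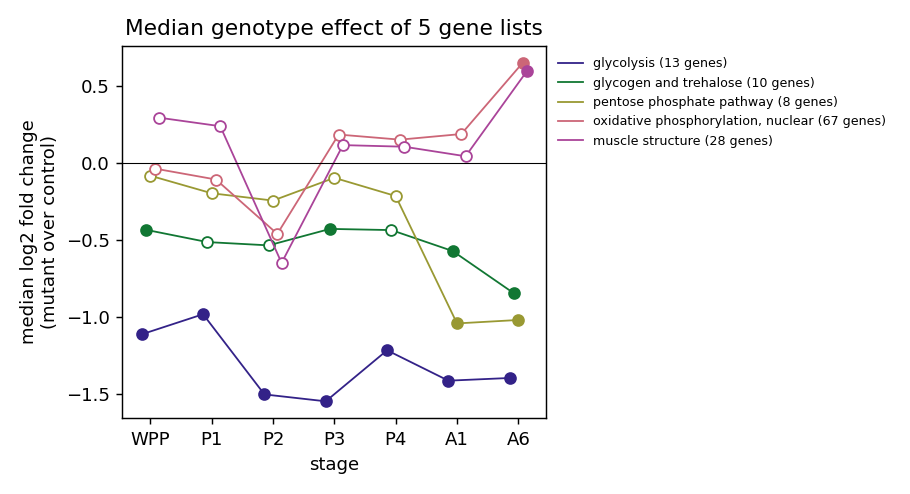
Median log2 fold change of ERR mutant against control for 5 gene lists at the 7 stages. Filled points mark list tests with adjusted p under 0.05 with an estimated correlation, as for glycolysis at every stage, where medians lay between -1.55 and -0.98.

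Genes that store and release glycogen or make trehalose, the blood sugar of insects, were lower at the same stages in part. Of 10 members, 3, 4, 4, 4, 3, 5 and 5 fell from WPP to A6 (6, 6, 5, 5, 4, 6 and 6 adjusted over the list alone). AGBE, the glycogen branching enzyme, was at 515.9 ± 74.9 CPM in A1 controls and 92.8 ± 20 CPM in A1 mutants (5.56-fold lower, adjusted p = 1.4e-12). UGP, which makes the UDP-glucose used for glycogen, was 4.23-fold lower at A6, at 404.8 ± 66.7 against 95.7 ± 5.71 CPM. The list was called at each stage with the preset correlation, and at WPP, P3, A1 and A6 with an estimated one (adjusted p = 0.00606, 1.4e-05, 0.00173 and 0.00680 with an estimated correlation). At P1, P2 and P4 it was not (adjusted p = 0.162, 0.387 and 0.397 with an estimated correlation). Tps1, trehalose-6-phosphate synthase, went the other way at P4, at 183.7 ± 74.5 against 336.3 ± 35.8 CPM (adjusted p = 0.0456). That call was lost without any 1 of control replicates 1 and 2 and mutant replicates 1, 2 and 3 (adjusted p from 0.0742 to 0.429) and with only the 6 P4 libraries (0.355).

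The number of genes called between genotypes differed widely among stages. At WPP 89 of 13672 genes were called (28 higher, 61 lower), at P1 109 (23 and 86), at P2 1582 (380 and 1202) and at P3 61 (24 and 37). At P4 117 genes were called (62 and 55), at A1 397 (127 and 270) and at A6 1562 (840 and 722). In all, 3043 genes were called at 1 stage or more, 633 at more than 1, and 247 in both directions at different stages. The number of calls is not a measure of effect size. Called genes that changed at least 2-fold numbered 47, 68, 529, 43, 76, 155 and 456 from WPP to A6. These counts were also highest at P2 and A6, and they depend on the calls.

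**Figure D3:**
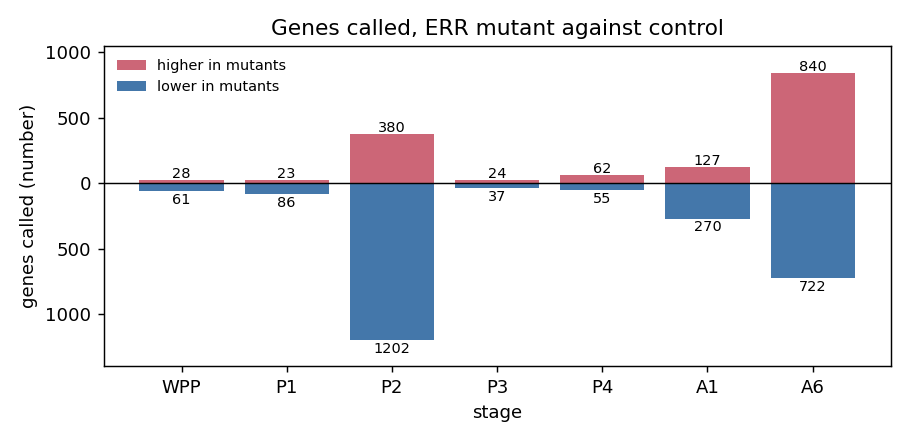
Number of genes called higher and lower in the ERR mutant at each stage (edgeR quasi-likelihood test, adjusted p under 0.05). P2 with 1582 genes and A6 with 1562 stand above the other stages, which range from 61 to 397.

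At WPP, 13 of the 61 lower genes were the glycolysis list, and Pglym78, phosphoglycerate mutase, was at 56.6 ± 7.44 CPM in controls and 13.7 ± 1.76 CPM in mutants (4.13-fold, adjusted p = 2.1e-11). GlyP, glycogen phosphorylase, was 3.41-fold lower at 74.1 ± 18.6 against 21.8 ± 3.16 CPM. GstT3, a glutathione S-transferase, rose from 16.9 ± 1.13 to 48.1 ± 5.80 CPM (adjusted p = 2.7e-07), and it was the 1 gene called higher of the 35 in its family. mthl7 was at 0 CPM in controls and 19.2 ± 2.37 CPM in mutants, at least 128-fold higher. eIF4E7 had 316 counts in the 3 control libraries and 1 in the 3 mutant libraries (adjusted p = 2.8e-10). Genes of sugar digestion in the gut had a median log2 fold change of -0.79 with 1 of 14 called lower, 3 adjusted over the list alone (adjusted p = 0.161 with an estimated correlation). Without control WPP replicate 2 the number of calls was 46 (13 higher), and without mutant WPP replicate 2 68 (13 higher).

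At P1 the lower genes again included 11 glycolysis enzymes, among them Gapdh2 at 180 ± 11.1 CPM in controls and 59.4 ± 6.60 CPM in mutants (3.03-fold, adjusted p = 4.0e-10) and PyK, pyruvate kinase, at 93.9 ± 7.08 against 46.5 ± 5.47 CPM. GlyS, glycogen synthase, was at 74.1 ± 2.48 against 44.3 ± 2.40 CPM (1.67-fold lower, adjusted p = 0.00308). lncRNA:CR44549 was at 0 CPM in controls and 11.7 ± 0.831 CPM in mutants, at least 86.7-fold higher. CG17778 rose 3.55-fold, from 4.91 ± 0.405 to 17.4 ± 2.13 CPM. Testis genes had a median log2 fold change of -0.72 with 0 of 25 called by edgeR, also when adjusted over the list alone (adjusted p = 0.723 with an estimated correlation). Mutant P1 replicate 1 held the testis transcript Mst87F at 1.08 CPM against 65.5 to 100.7 CPM in the other 5 P1 libraries. It also held roX2, an RNA of male dosage compensation, at 0.270 CPM against 9.09 to 18.7 CPM. That library adds to the spread of such genes in the fit of all libraries, so their missing calls carry little weight. Without mutant P1 replicate 1, 103 genes were called at P1, 88 of them shared with the 109. The 23 higher genes became 11 without control P1 replicate 2 and 35 without control P1 replicate 1. With only the 6 P1 libraries fitted, 19 were called. With DESeq2's size factors in edgeR the split was 74 higher and 81 lower, with DESeq2 120 and 111, and with the deposited factors 75 and 84.

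At P2 genes of energy metabolism beyond glycolysis were also lower, although no list in this paragraph passed with an estimated correlation. Genes of the mitochondrial genome did not share the fall. Their median member was at 0.015 ± 0.366 log2 units against control WPP in controls and 0.379 ± 0.578 in mutants. Of 67 nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, 57 fell (60 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.319 with an estimated correlation). Of 21 genes of pyruvate dehydrogenase and the TCA cycle 16 fell (20 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation), such as Acon, aconitase, at 674.3 ± 37.7 against 415.6 ± 52.9 CPM. Of 75 mitochondrial ribosomal proteins 32 fell (46 adjusted over the list alone; adjusted p = 0.370 with an estimated correlation). Of 28 muscle structure genes 22 fell (27 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation), and Act79B, a muscle actin, was 2.28-fold lower at 919.6 ± 99.8 against 404.1 ± 80 CPM. In controls the medians of the nuclear oxidative phosphorylation and muscle lists rose from P1 to P3. They went from -0.001 and -0.11 to 2.453 and 5.556 log2 units against control WPP. P2 mutants stood earlier on the control course (2.80 against 3.01), which is weighed below. Ldh, lactate dehydrogenase, fell 3.89-fold, from 57.1 ± 6.06 to 14.7 ± 0.737 CPM. The same libraries differed in RNAs of male dosage compensation, without a call: lncRNA:roX1 was at 295.9 to 474 CPM in mutants and 126.6 to 281.4 CPM in controls (adjusted p = 0.342), and lncRNA:roX2 at 18.4 CPM or more in mutants and 13.9 CPM or less in controls (adjusted p = 0.128). The testis transcript Mst87F overlapped, at 111.2 to 188.9 against 69.3 to 146.5 CPM. Mutant P1 replicate 1, very low in these RNAs, entered the same fit and added to their spread. The missing calls for roX1 and roX2 therefore carry little weight.

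Single genes of the cuticle, ecdysone and cell cycle lists were also called at P2, and none of these lists was. Cpr72Ec, a cuticle protein, was at 141.6 ± 86.7 CPM in controls and 0.690 ± 0.0913 CPM in mutants, and y, which is needed for black pigment, at 94.8 ± 77.3 against 0.490 ± 0.278 CPM (adjusted p = 2.3e-12 and 1.1e-08). Of 90 cuticle genes 16 fell and 10 rose (18 and 10 adjusted over the list alone), among the latter Cpr49Ab at 3.28 ± 1.10 against 19.2 ± 0.724 CPM, and the list test was not passed (adjusted p = 0.577). Of 20 ecdysone genes 2 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.440), and Cyp18a1, which breaks down the moulting hormone ecdysone, rose 2.38-fold, from 33.3 ± 8.86 to 79.3 ± 19.6 CPM. Of 22 cell cycle genes 3 rose (3 adjusted over the list alone), led by stg, the Cdc25 phosphatase, at 13.1 ± 2.61 against 25.4 ± 1.52 CPM, and the list was not called (adjusted p = 0.112). CG42367 was at 37.7 ± 28.3 CPM in controls and 0 in mutants, at least 221-fold lower, although not called with only the 6 P2 libraries (adjusted p = 0.0666). Those 6 libraries alone called 728 genes. Without mutant P2 replicate 2 the number of calls was 1030 (361 higher). The 380 higher genes became 244 without control P2 replicate 2, 245 without mutant P2 replicate 3 and 584 without mutant P1 replicate 1.

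At P3, where 61 genes were called, the 37 lower genes included 11 of glycolysis and 4 of glycogen and trehalose metabolism. Pgm was at 205.7 ± 15.3 CPM in controls and 33.4 ± 4.44 CPM in mutants (6.15-fold, adjusted p = 4.3e-14), and AGBE at 53.6 ± 4.24 against 8.89 ± 0.802 CPM (adjusted p = 2.9e-11). UGP was 3.02-fold lower at 82.8 ± 9.28 against 27.4 ± 4.51 CPM. Cpr72Ea, a cuticle protein, rose from 9.98 ± 2.19 to 37.9 ± 11 CPM, the 1 called gene of the 90 in its list (2 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation). In the oxidative phosphorylation list 0 of 67 genes were called by edgeR, over all genes and adjusted over the list alone, with a median of 0.18 (adjusted p = 0.381 with an estimated correlation). With only the 6 P3 libraries 26 genes were called, 6 higher and 20 lower. The 24 higher genes became 11 without mutant P3 replicate 1, and 16 without control P3 replicate 1 or 2.

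At P4 the lower genes included some of the male accessory gland, which makes seminal fluid proteins, and whose median member stayed at its level in WPP controls up to P3 in both genotypes. Of 25 such genes 8 fell (14 adjusted over the list alone; adjusted p = 0.0666 with an estimated correlation), and Acp36DE was 6.17-fold lower at 79.7 ± 37.9 against 12.9 ± 0.927 CPM (adjusted p = 2.3e-06). The 3 P4 controls also differed among themselves in male RNAs, with roX1 at 207, 365 and 455.5 CPM and Acp26Aa at 1.69, 5.52 and 10.2 CPM in the same libraries, against 239.8 to 257.7 and 0.491 to 0.997 CPM in mutants. Gapdh2 was at 813.1 ± 50.9 CPM in controls and 194 ± 5.54 CPM in mutants. Lectin-galC1, a galactose-binding lectin, rose 5.28-fold, from 19.8 ± 1.92 to 104.4 ± 19.2 CPM, and FASN1, a fatty acid synthase, 1.58-fold, from 98.2 ± 9.88 to 155.7 ± 5.78 CPM (adjusted p = 1.3e-08 and 6.2e-04). FASN1 was the 1 called gene of the 16 for fatty acid and triglyceride synthesis (2 higher adjusted over the list alone; adjusted p = 0.678 with an estimated correlation). The count of calls was 45 without control P4 replicate 1, 70 without control P4 replicate 2, 274 without control P4 replicate 3 and 54 without mutant P4 replicate 1. With only the 6 P4 libraries it was 44, 18 higher and 26 lower, and with DESeq2 213.

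At A1 the pentose phosphate pathway, which makes NADPH and ribose, was lower together with glycolysis. Of its 8 genes 6 fell (6 adjusted over the list alone), with a median of -1.04 (adjusted p = 5.4e-06 with an estimated correlation). Taldo, transaldolase, was at 261.9 ± 23.6 CPM in controls and 51.8 ± 2.55 CPM in mutants (5.06-fold, adjusted p = 1.4e-12), and CG8036, a transketolase, at 678.2 ± 105 against 236.4 ± 6.29 CPM. Sodh-1, a sorbitol dehydrogenase, fell 11.6-fold, from 299.5 ± 35.7 to 25.8 ± 4.31 CPM. ATPCL, which makes cytosolic acetyl-CoA for lipid synthesis, was 1.62-fold lower at 324.1 ± 37.1 against 199.6 ± 10.1 CPM. Its list, fatty acid and triglyceride synthesis, did not share the fall and did not pass with an estimated correlation. The list median was 0.405 to 0.545 log2 units against control WPP in A1 mutants and 0.299 to 0.335 in A1 controls. Of 14 sugar digestion genes 4 rose (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0932 with an estimated correlation). CG13215 rose 13.8-fold, from 1.21 ± 0.285 to 16.9 ± 2.23 CPM. Calls numbered 198 without control A1 replicate 1, 203 without control replicate 2, 718 without mutant A1 replicate 1, 193 without mutant replicate 2 and 210 without mutant replicate 3. The split was 186 higher and 233 lower with DESeq2's size factors in edgeR, 226 and 286 with DESeq2, and 184 and 241 with the deposited factors.

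At A6 the lists of glycolysis and the pentose phosphate pathway were lower, while those of nuclear oxidative phosphorylation and muscle structure were higher. Pepck1, which catalyses the committed step of glucose synthesis, fell 39.2-fold, from 383.4 ± 84.1 to 9.79 ± 2.13 CPM (adjusted p = 1.5e-17). CG45087, annotated over the same place, had identical values, so the pair counts as 1 measurement. Of the 8 pentose phosphate genes 6 fell (7 adjusted over the list alone; adjusted p = 7.0e-04 with an estimated correlation). Of 67 nuclear oxidative phosphorylation genes 59 rose (61 higher and 1 lower adjusted over the list alone), with a median of 0.65 (adjusted p = 0.0278 with an estimated correlation), as for ATPsynD, a subunit of ATP synthase, at 250.4 ± 10.6 against 482.6 ± 29.6 CPM. Of 28 muscle genes 20 rose (23 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.0461 with an estimated correlation). Act88F, the actin of the indirect flight muscle, rose 10.8-fold, from 53.0 ± 6.89 to 570 ± 66 CPM, and TpnC4, a flight muscle troponin C, 6.55-fold, from 87.7 ± 9.58 to 574.6 ± 12.9 CPM. In controls the oxidative phosphorylation and muscle lists fell from A1 to A6, and A6 mutants lay in between. The oxidative phosphorylation median was 2.789, 1.757 and 2.387 log2 units above control WPP in A1 controls, A6 controls and A6 mutants. The muscle median was 5.076, 3.209 and 3.84. A6 mutants also stood earlier on the control course (6.88 against 6.97), and whether a delay accounts for these rises was not tested. Of 21 TCA cycle genes 10 rose (16 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation). The sugar digestion list had a median of 0.46 with 2 of 14 called higher and 2 lower (5 and 2 adjusted over the list alone), and was not called (adjusted p = 0.122).

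Genes of fat and gut lists were also called at A6. Lsd-1, a lipid droplet protein, was at 178.1 ± 24.2 CPM in controls and 33.3 ± 4.40 CPM in mutants (5.34-fold lower, adjusted p = 7.2e-08), and bmm, a triglyceride lipase, was 2.14-fold higher at 126.1 ± 15.4 against 58.9 ± 6.55 CPM in controls. Of 16 genes of fatty acid and triglyceride synthesis 3 rose and 6 fell (5 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.368). Of 17 genes of lipolysis and fatty acid oxidation 11 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.483 with an estimated correlation). Of 28 midgut proteases 16 fell (19 adjusted over the list alone; adjusted p = 0.0786 with an estimated correlation), such as Jon65Aiv at 1149 ± 37.6 against 312.9 ± 67.2 CPM, although similar genes of this family can share reads. Of 25 accessory gland genes 15 fell (17 adjusted over the list alone; adjusted p = 0.319 with an estimated correlation), such as Dup99B at 513.7 ± 32.2 against 176.2 ± 28.1 CPM. With DESeq2's size factors in edgeR the A6 split was 653 higher and 913 lower, with DESeq2 684 and 938, and with the deposited factors 640 and 870. The 6 A6 libraries alone called 3218 genes, and 906 were called without mutant A6 replicate 2.

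Whether the genotype effect itself differed among stages was tested directly. The interaction of genotype and stage was called for 1690 genes. The smallest p belonged to Pepck1 (adjusted p = 3.0e-14), followed by Act88F and CG9914 (6.5e-11 each). CG9914 had a log2 fold change of -0.78 (SE 0.201) at P2 and -3.07 (SE 0.165) at A6. The effect at A1 and A6 differed from that at P1 to P4 for 660 genes, 364 with a higher and 296 with a lower log2 fold change at the A stages. The majority turned with other scalings, to 362 and 399 with DESeq2's size factors in edgeR, 403 and 461 with DESeq2, and 357 and 409 with the deposited factors. Sodh-1 was among the latter, with a difference of -2.92 (SE 0.504, adjusted p = 2.7e-04), and Cpr72Ec among the former, with a difference of 2.52 (SE 0.354, adjusted p = 2.8e-05), as its log2 fold change was -7.64 at P2 and 1.02 at A6. P2 and A6 shared 128 lower and 35 higher genes, against 63.5 and 23.3 for independent lists, while 202 genes were called in opposite directions. The number of opposite calls for independent lists was not computed, so the excess of shared calls does not show that the effects at P2 and A6 agree. Across all genes tested, the log2 fold changes at P2 and A6 had a Pearson correlation of 0.103 and a Spearman correlation of -0.053.

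Between neighbouring control stages 3333 to 6381 genes were called, more than between genotypes at any stage. Between WPP and P1, 6381 genes were called (3498 higher, 2883 lower). Genes of the salivary glue and the Eig71E cluster, made for pupariation, fell for 14 of 16 members (15 adjusted over the list alone; adjusted p = 0.00844 with an estimated correlation). Cpr72Ea rose from 0.153 ± 0.265 to 5279 ± 235 CPM, and CG18735 from 0 to 826 ± 68.5 CPM, at least 5480-fold. Between P1 and P2, 6125 genes were called (2865 and 3260). Of 28 muscle genes 27 rose and 1 fell (27 and 1 adjusted over the list alone; adjusted p = 0.00352 with an estimated correlation), and all 22 cell cycle genes fell (22 adjusted over the list alone; adjusted p = 1.0e-05 with an estimated correlation). Osi3, of the Osiris family of membrane proteins, rose from 0.231 ± 0.0940 to 7194 ± 1700 CPM. Between P2 and P3, 4995 genes were called (2133 and 2862), and 62 of 90 cuticle genes rose while 11 fell (64 and 12 adjusted over the list alone; adjusted p = 5.1e-06 with an estimated correlation). Cpr76Bb rose from 0 to 840 ± 103 CPM, at least 5440-fold. The P2 to P3 split was 2626 higher and 2134 lower with DESeq2's size factors in edgeR, 2670 and 2110 with DESeq2, and 2576 and 2126 with the deposited factors.

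Between P3 and P4, 5123 genes were called in controls (2368 higher, 2755 lower). Photoreceptor genes rose for 14 of 16 members (14 adjusted over the list alone; adjusted p = 0.00467 with an estimated correlation), and 56 cuticle genes fell while 14 rose (59 and 14 adjusted over the list alone; adjusted p = 0.0463 with an estimated correlation). Osi18 fell from 698.8 ± 187 to 0 CPM, at least 3590-fold. Between P4 and A1, 5322 genes were called (2220 and 3102), and sugar digestion genes rose for 13 of 14 members (13 adjusted over the list alone; adjusted p = 1.8e-04 with an estimated correlation). EbpII, a protein of the male ejaculatory bulb, rose from 0 to 543.8 ± 155 CPM, at least 2810-fold. Between A1 and A6, 3333 genes were called (1320 and 2013). In this step 61 of 67 oxidative phosphorylation genes fell (61 adjusted over the list alone; adjusted p = 0.0307 with an estimated correlation), and so did 25 of 28 muscle genes while 1 rose (25 and 2 adjusted over the list alone; adjusted p = 4.0e-04 with an estimated correlation). Fbp1, a receptor of the larval fat body, fell from 115.5 ± 51.7 to 0 CPM, at least 703-fold. Of 13 glycolysis genes 11 rose from P1 to P2 (11 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation) and 13 fell from A1 to A6 (13 adjusted over the list alone; adjusted p = 0.0876 with an estimated correlation).

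Placed on the control course, where WPP to A6 are numbered 1 to 7, all 42 libraries lay nearest to their own stage. P2 mutants were at 2.80 ± 0.0421 and P2 controls at 3.01 ± 0.0537, a difference of -0.208, with no overlap. A6 mutants were at 6.88 ± 0.0190 and A6 controls at 6.97 ± 0.0167, a difference of -0.0833. Both had p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 libraries allow, so neither could pass 0.05. At the other 5 stages the differences lay between -0.0213 and 0.0823, with exact permutation p of 0.6 or more. By construction no library could be placed before 1 or after 7, so an earlier place at WPP or a later one at A6 could not be seen. At A1, control replicate 3 (6.18) lay with mutant replicates 2 and 3 (6.16 and 6.22), and mutant replicate 1 (5.95) with control replicates 1 and 2 (5.95 and 5.94).

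**Figure D4:**
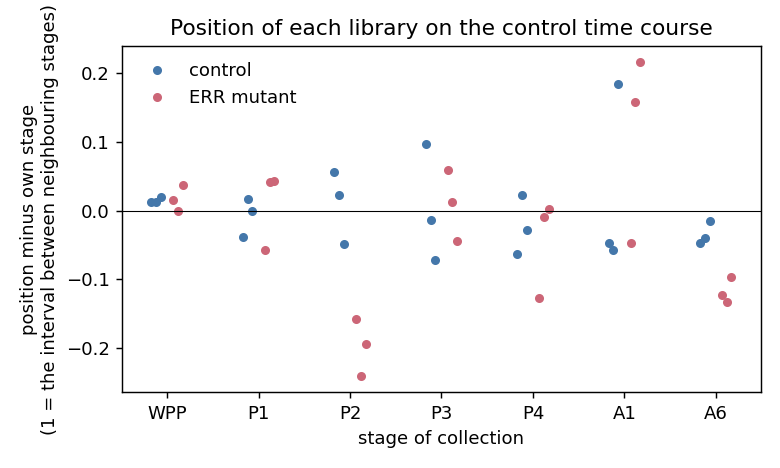
Position of each library on the control course minus the number of its own stage, by genotype. The 3 P2 mutants lie below the 3 P2 controls, by -0.208 on average, on an axis where 1 is the distance between neighbouring stages.

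A pair of genes beside ERR differed at most stages. mthl7 (3L, 8178675 to 8180514) was at 16.5 ± 0.939 CPM in A1 mutants and 0 in A1 controls, at least 77.5-fold higher (adjusted p = 1.4e-12). Uxs, UDP-xylose synthase (3L, 8180923 to 8183369), overlaps the end of ERR on the other strand, so the pair could share reads if strand was not used in counting. Uxs was at 8.67 ± 2.67 CPM in P2 controls and 1.58 ± 0.510 CPM in P2 mutants (log2 fold change -2.45, SE 0.327, adjusted p = 1.5e-06), and was called lower at 6 stages. Of the 24 tested genes within 50 kb of ERR, these 2 were called in 1 direction at 5 stages or more.

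**Figure D5:**
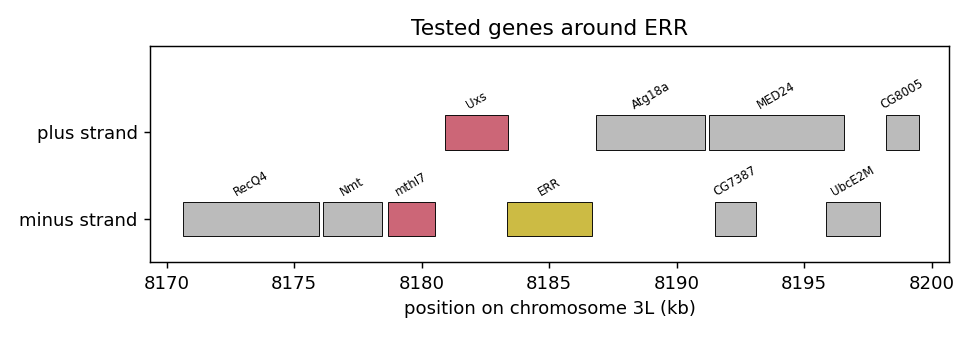
Genes around ERR on chromosome 3L (dm6 coordinates), with ERR in yellow, other tested genes in grey, and genes called in 1 direction at 5 stages or more in red. The red genes are mthl7, on the minus strand from 8178675 to 8180514, and Uxs, on the plus strand, which ends at 8183369 within ERR.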

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

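Every test in this part was chosen after the result was seen, except the interaction counts, the thinning of libraries to equal totals and the splits of the libraries.

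The genotype effect differed among stages for 1690 genes, and between the A and P stages for 660 genes. In 48 draws of genotype labels within stages, the real one included, the highest other draw gave 313 and 361 genes. The draws also break any genotype effect that is equal at all stages. They therefore set the counts against no genotype effect at all, and cannot show that the effect differs among stages. Lists that were lower at P2 and higher at A6 drew attention, so the difference of the genotype effect between these stages was computed; since the lists were picked for this pattern in the same libraries, its p-values add no support to it. Nuclear oxidative phosphorylation genes had a median difference of 1.11 log2 units with 62 of 67 members called higher (camera adjusted p = 1.045e-97, 0.00306 with an estimated correlation). Muscle structure genes had a median difference of 1.27 with 25 of 28 members called higher (adjusted p = 1.909e-56, 0.00251 with an estimated correlation). TCA cycle genes had 19 of 21 called higher (adjusted p = 1.189e-25, 0.0249 with an estimated correlation).

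The first pattern weighed is the 1582 genes called at P2, where roX1 also stood higher in all 3 mutants (295.9 to 474 against 126.6 to 281.4 CPM), so that a different share of males stays open as an untested explanation. Unequal depth of the 6 P2 libraries is argued against, since the 6-library fit made 94.5% as many calls after thinning them to equal totals (a median of 688 over 5 thinnings, against 728 before); whether these were the same genes was not counted. A candidate explanation is that P2 mutants stood earlier in development than P2 controls: of the 1582 genes, 73.1% went against the change of controls from P1 to P3, against 50.6% of all genes tested. That share lay between the bounds set for and against this explanation, and at stages with smaller position differences it lay near that of all genes at P1, P4 and A1 (49.5%, 62.4% and 41.3% against 51.7%, 61.2% and 40.1%) and above it at P3 (80.3% of 61 genes against 56.7%), so for these genes as a set a delay and a direct effect of the genotype cannot be told apart. For the glycolysis genes a delay at P2 is argued against as the whole cause, because their median log2 fold change stayed at -1.22 or below at P3, P4 and A1, where mutant and control positions differed by 0.00533, -0.0213 and 0.0823 stages. The nuclear oxidative phosphorylation and muscle structure lists were not lower at P3, so a delay at P2 stays open for them. Their medians stood at 2.645 and 5.594 log2 units above control WPP in P3 mutants, against 2.453 and 5.556 in P3 controls.

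The second pattern is mutant P1 replicate 1. Its roX2 level was 6.08% of the lowest level in the other 41 libraries, roX1 was at 4.19 CPM against 220.4 to 317.3 CPM in the other P1 libraries, and the testis list summed to 36.5 CPM against 1570 to 2120 CPM. Female animals in a set of otherwise male libraries may account for this, and the labels used here do not settle the sex of the animals. For A1 and A6 the markers speak for males in both genotypes. In every A1 and A6 library the yolk protein genes Yp1 and Yp2 lay at 2.42 CPM or less, and Acp26Aa of the accessory gland at 203.6 CPM or more. At P1 these markers are near 0 in all libraries and decide nothing. Animals of another stage are argued against: over all genes tested its Spearman correlation was 0.838 with control P1 and 0.794 with the next control stage, WPP, a gap of 0.045, and over genes that change between control stages 0.974 with P1 and 0.857 with the next, P2. No biological explanation from the genotype was tested, since the other 2 mutant P1 libraries did not share the pattern.

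The third pattern is the 18 genes outside the lists that were called in 1 direction at 5 or more stages. Of these, 61.1% (11) lie on the X, against 15.4% of the tested genes (Fisher's exact p = 1.26e-05), among them eIF4E7, Kmn1 and CG12661. Different X chromosomes in the control and mutant stocks may account for that part, although Gss1 and Gss2, which have identical values, and Kmn1 and CG11699, which overlap, count as 4 of the 11, and the Fisher test takes them as separate genes. Of 24 tested genes within 50 kb of ERR, 2 are in the set, mthl7 and Uxs (8.33% against 0.249% of all genes, Fisher's exact p = 0.00162), so a change in the DNA around ERR that acts on its neighbours may account for those. An effect of ERR on these genes stays open, since the design does not separate it from other differences between the stocks, the hsFLP transgene among them.

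For single stages, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In the 6-library fits the real split and the highest other gave 61 and 1 genes at WPP, 19 and 0 at P1, 728 and 0 at P2, 26 and 0 at P3, 44 and 0 at P4, 333 and 274 at A1, and 3218 and 0 at A6. The 274 genes at A1 came from exchanging control A1 replicate 3 with mutant A1 replicate 1, which sorts these libraries by position on the control course (5.94 to 5.95 against 6.16 to 6.22), so it points to a structure of the samples. For the control steps the real counts from WPP to A6 were 7359, 5923, 3762, 4262, 4404 and 3966, and the highest other was 0 in each.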

How the results depend on the processing

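Scaling by the deposited factors, DESeq2 for ERR, and leaving mutant P1 replicate 1 out of comparisons that do not use it were chosen after the data were seen. Of 4529 alternatives for single genes and lists, 3943 kept direction and side of the threshold, 586 kept direction and were no longer called, and 0 reversed. All of these genes and lists were called in the main fit, and many genes were picked for large folds. The lack of reversals therefore follows in part from the choice. Requiring 2-fold changes left 47 genes at WPP, 68 at P1, 529 at P2, 76 at P4, 155 at A1 and 456 at A6, which follows from its construction. DESeq2 called 231 genes at P1 and 213 at P4, against 109 and 117, and the cause was not tested. With only the 6 libraries compared, 19 genes were called at P1, 728 at P2, 26 at P3, 44 at P4 and 3218 at A6, with fewer residual degrees of freedom at every stage, and the cause of the rise at A6 was not tested. That fit also moved the median log2 change of all genes from WPP to P1 in controls by -0.182, so changes of that step are relative to a scaling that differs by this much. The ERR difference at P3 was -0.79 with DESeq2's size factors in edgeR (adjusted p = 0.0498, from 0.101), close to the threshold. Of 81 list calls, 15 held with an estimated correlation and fry called 45, which asks another question. Leaving out 1 library gave 46 to 132 genes at WPP, 1030 to 1983 at P2, 45 to 274 at P4, 193 to 718 at A1 and 906 to 1813 at A6. Without mutant P1 replicate 1 the counts at WPP, P2, P3, P4, A1 and A6 were 132, 1983, 75, 147, 534 and 1813. Without the low-count filter, and with the deposited factors, each genotype and control count stayed within 1.5 times its reported value. Depth limits genes near 1 CPM, which rest on a few counts in each library. No paired analysis was possible because the labels give no replicate numbers.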

Other observations

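All tests of single genes in this part are those of the report's fits, and no further test was chosen after the result was seen.

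Single genes of further lists were called at A6, where 11.4% of all genes tested were called, and none of the lists in this paragraph and the next passed with an estimated correlation. Of 16 photoreceptor genes 6 rose (7 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation), with Rh5, a blue-sensitive rhodopsin, at 10.7 ± 2.42 CPM in controls and 43.8 ± 0.524 CPM in mutants. Of 93 cytosolic ribosomal protein genes 16 rose (49 adjusted over the list alone; adjusted p = 0.784 with an estimated correlation), and of 75 mitochondrial ones 8 rose (8 adjusted over the list alone; adjusted p = 0.864 with an estimated correlation). Of 79 cytochrome P450 genes 9 fell (9 adjusted over the list alone; adjusted p = 0.678 with an estimated correlation). Larval serum protein genes Lsp2 and Lsp1beta fell, 8.04-fold and 12.4-fold, 2 of 6 in their list (2 adjusted over the list alone; adjusted p = 0.723 with an estimated correlation). Of 15 amino acid genes 6 fell and 2 rose (8 and 3 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). fbp, fructose-1,6-bisphosphatase, fell 4.52-fold there. In the insulin and adipokinetic hormone list 3 of 16 rose and 2 fell (6 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.661). Thor, the fly 4E-BP and a target of foxo, rose 2.71-fold at A6, and AkhR, the receptor of adipokinetic hormone, fell 2.75-fold.

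Smaller groups were as follows. In the list for lactate and glycerol-3-phosphate, Ldh and Gpdh1, the cytosolic glycerol-3-phosphate dehydrogenase, fell at A6, 2 of 6 (2 adjusted over the list alone), and the list was not called (adjusted p = 0.112). Of 10 haemocyte genes 2 fell at A6 (5 adjusted over the list alone; adjusted p = 0.678 with an estimated correlation), with PPO1, a prophenoloxidase, at 15.5 ± 2.94 against 2.54 ± 0.636 CPM. Of 16 neuron genes 2 rose at A6 (3 adjusted over the list alone; adjusted p = 0.814 with an estimated correlation), and 2 of 32 proteasome genes fell (2 adjusted over the list alone; adjusted p = 0.814 with an estimated correlation). Of 12 genes of the mitochondrial genome 1 fell at A1 (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.730 with an estimated correlation).

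Further lists that were not called at A6 follow with their called genes. In the antimicrobial and Turandot list 6 of 38 fell (6 adjusted over the list alone; adjusted p = 0.303 for the list), with PGRP-SB1, a peptidoglycan recognition protein, at 22.8 ± 5.78 against 5.29 ± 1.30 CPM. In the ecdysone list 2 of 20 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.318), in the heat shock list 2 of 16 rose (3 adjusted over the list alone; adjusted p = 0.878), and in the glutathione S-transferase list 2 of 35 rose and 1 fell (2 and 0 adjusted over the list alone; adjusted p = 0.869). The lists for circadian clock, melanin and pigment, ovary and eggshell, and testis-type paralogs of oxidative phosphorylation genes had 1 called gene each, of 9, 17, 8 and 20 (adjusted p = 0.461, 0.0907, 0.461 and 0.796). The clock median, in log2 units against control WPP, stood higher in mutants at P2 (1.588 to 1.771 against 0.559 to 1.289). It did so at P3 (1.958 to 2.261 against 0.949 to 1.427), and stood lower at A6 (3.229 to 3.268 against 3.59 to 3.694). With an estimated correlation the clock list passed at none of these stages, and the cause of the shifts was not tested. The list of 3 male dosage compensation RNAs was not called at any stage (adjusted p = 0.655 at A6), although its members lncRNA:roX1 and lncRNA:roX2 did not overlap between genotypes there, at 675.2 to 824.1 against 488 to 547.4 CPM and 16.6 to 22.3 against 9.76 to 12.8 CPM (adjusted p = 0.648 and 0.321). Mutant P1 replicate 1, very low in roX1 and roX2, entered the same fit and added to their spread, so these missing calls carry little weight.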
